A study of Homo sapiens with 16 samples.

How the data were processed

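Polyadenylated RNA was sequenced for 16 libraries of Jurkat cells, and the values used here are those the authors deposited. Per the submitters' processing notes, reads were quantified with Salmon and compared with DESeq2 on the hg38 genome build. The versions of these tools and the strandedness of the libraries are not given in the sources used here. For each library the authors deposited estimated counts (expected counts of reads per transcript, which need not be whole), TPM values, which are scaled to the same total in each library, and effective transcript lengths, per the file headers. A gene-level TPM table of all libraries, made by the authors, was also deposited. Its 16 columns of values each matched 1 library, 0 columns of values were left unused, and it was used to check that gene sums of the transcript TPM gave the same values.

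Transcript identifiers and lengths were checked against GENCODE release 29, and 205870 of 205870 transcripts matched, in 58295 genes. Estimated counts were summed per gene and rounded to whole numbers. Libraries were grouped by the line and the treatment in their labels into 6 groups, with 2 wild-type, 3 dE9 and 3 iE9 libraries for each treatment. Total estimated counts ran from 14536537 to 21888896 per library. No pair of replicates agreed within sampling noise, since the lowest chi-square per degree of freedom was 7.55, and each library was counted as 1 sample.

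Genes were tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood F test, two-sided, on all 16 libraries with 1 coefficient per group. The spread was therefore estimated over the 6 groups, with TMM normalization factors and robust estimation off. The filterByExpr rule kept 18073 of 33304 genes with a count. The common biological coefficient of variation was 31.8%, and the median prior degrees of freedom were 4.8. Genes with a Benjamini-Hochberg adjusted p under 0.05 within a comparison are said to have changed, and every adjusted p of a gene in the text comes from this test unless another tool is named. Fold changes are on the log2 scale with their standard error (SE), and levels are TMM-scaled counts per 1e6 (CPM) with the standard deviation (SD) between libraries. The comparisons were PMA against unstimulated cells in each line, the lines against each other within each treatment, and the differences between lines in their response to PMA.

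The share of HDAC7 exon 9 was the TPM of transcripts that hold the exon divided by the TPM of transcripts that span it, with or without the exon. Groups were compared by an exact permutation test of the difference in mean share, two-sided. Where a group had 0 counts of a gene, a fold was computed against a floor of 3 counts per library and is given as a lower bound. Where it had 1 to 3 counts, the ratio is given with its 95% counting interval. Intervals and floors cover counting error only, since PCR copies are not independent molecules.

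The comparisons, the gene lists, the rule for naming genes and most alternatives were chosen before the data were examined. HDAC7, CD28, CD69, IL2RA, CD5, NR4A1 and CD3E were always named. In the wild-type PMA comparison and in iE9 against dE9, the 10 genes per direction with the largest fold were named, and in the other comparisons the 5 per direction. These genes had an adjusted p under 0.05, no overlap between the libraries of the 2 groups, a mean of at least 5 CPM in the higher group, and a symbol that was neither clone-based nor a pseudogene. From each list up to 4 called members with the smallest adjusted p were named, or up to 2 members with the highest mean CPM where fewer than 2 were called. Genes shared between comparisons were named by the largest smaller fold.

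The 34 lists covered the HDAC family and co-repressors, 14-3-3 proteins, the MEF2 and NR4A axis, the T cell receptor complex, T cell co-receptors and surface molecules, activation markers, AP-1 and EGR factors, NF-kB members and targets, cytokines and chemokines, and PKC signalling. They further covered MAPK feedback regulators, thymocyte transcription factors and rearrangement genes, the NOTCH pathway, the cell cycle, cyclin-dependent kinase inhibitors and D cyclins, ribosome biogenesis, cholesterol and fatty acid synthesis, glycolysis, the interferon response, and antigen presentation. The remainder covered the unfolded protein and integrated stress response, p53 targets, apoptosis regulators, lymphocyte adhesion, splicing regulators, histone-modifying enzymes, mitochondrially encoded genes, replication-dependent histones, and markers of natural killer, B, myeloid, erythroid, epithelial, and fibroblast or endothelial cells. Lists with at least 5 tested members were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry were run as alternatives. With an estimated correlation, 0 lists passed in any of the comparisons.

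Other alternatives were RLE normalization factors, the Wald test of DESeq2 1.42.0, no filter, a filter at a mean of 5 CPM, a fit of only the groups compared, a replicate block, an offset for transcript length, an adjusted p under 0.01, a change of at least 2-fold, and each library left out in turn. Leaving out an unstimulated or PMA wild-type library leaves 1 in that group, and that lone library is then assumed to vary like those of the other groups. A fit with a block for the library number within each line, limma voom with a variance weight per group, fits without both iE9 or both dE9 libraries numbered 1, and a fit without mitochondrially encoded genes were added after the data were seen.

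Pairing by label number was checked by correlating deviations from group means over genes. Same-numbered unstimulated and PMA libraries correlated at 0.30, 0.30 and 0.24 in dE9 and at 0.44, 0.23 and 0.19 in iE9, each over 0.1. The numbers pair dE9 libraries, but in iE9 clearly only number 1, since 2 with 3 reached 0.15. Same numbers gave 0.07 in the wild type and -0.07 to 0.12 between lines (-0.12 to 0.11 for differing numbers), and so pair nothing there.

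The tests were checked on simulated counts with known changes in 200 genes, drawn from each gene's mean level and dispersion and from the sizes of the real libraries. In the simulated wild-type PMA comparison (17431 genes), 7% of genes changed by a log2 value of 1 and 58% of those changed by 2 were called, with 1 false call. In simulated dE9 against wild type without PMA (17448 genes) these shares were 20% and 50%, with 3 false calls. In simulated iE9 against dE9 without PMA (17452 genes) they were 24% and 48%, with 1 false call. The remaining computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.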

Results

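The series followed gene expression in JSL1, a clone of Jurkat, an established human line of leukemic T cells. Cells were left unstimulated or were treated for 48 h with 20 ng/mL PMA, a phorbol ester that activates protein kinase C and is used to mimic part of T cell activation. Besides the wild type (WT), 2 lines edited with CRISPR were studied. One was made to lack exon 9 of HDAC7 (dE9) and one to include it (iE9). HDAC7 is a class IIa histone deacetylase that represses genes bound by MEF2 factors. The design describes the stimulated and unstimulated samples as different times, whereas the sample labels put all samples at 48 h, which was used here.

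There were 4 WT, 6 dE9 and 6 iE9 libraries, with 8 unstimulated and 8 PMA libraries in all. In units of 1e6 estimated counts, mean depth was 16.5 in unstimulated and 17.37 in PMA-treated WT cells, 18.93 and 19.96 in dE9, and 17.56 and 16.29 in iE9. Mitochondrially encoded genes took 3.0% to 6.39% of counts, except in the iE9 libraries numbered 1, with 9.17% in unstimulated and 12.81% in PMA-treated cells. Nothing in the labels says whether replicates came from separate cultures or clones, so p-values measure the spread between these samples, which may be technical.

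The first principal component (44% of variance) separated PMA-treated from unstimulated libraries in each line. The second held 13.4% and set all iE9 libraries, at -74 to -31, apart from the WT and dE9 libraries, at 1.3 to 45.6. PMA-treated dE9 library 1 lay at 28 on the first component, against 75 and 88 for the others of its group. Replicates were closest in WT, with a median SD over genes of 0.127 and 0.15 log2 units, against 0.256 and 0.389 in dE9 and 0.358 and 0.352 in iE9.

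**Figure D1:**
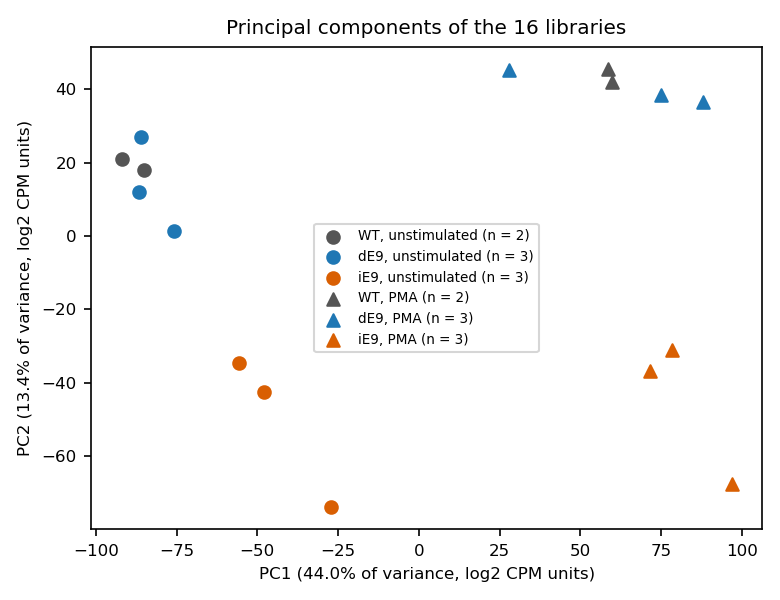
Each point is 1 library on the first (44%) and second (13.4%) principal components of log2 CPM, with lines in colour and treatment as the marker shape. PMA-treated libraries lie to the right and iE9 libraries low.

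HDAC7 was examined first, since it checks the labels. Exon 9 lies in the coding region on chromosome 12 (47795906 to 47796016, minus strand, hg38), is 111 nt long and encodes 37 codons. The gene (ENSG00000061273, 12: 47782722 to 47833132) has 30 annotated transcripts, of which 5 hold the exon and 5 span it without holding it. The exon 9 share was 47.04% ± 0.63 (SD, n = 2) in unstimulated WT and 48.42% ± 7.55 (n = 2) in PMA-treated WT. It was 3.45% ± 3.46 and 0.23% ± 0.39 (n = 3 each) in dE9, so the exon was nearly absent from the libraries of that line. In the iE9 libraries it was 61.63% ± 11.9 without PMA and 49.86% ± 11.42 with PMA (n = 3 each).

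The iE9 share lay 58.18 percentage points above dE9 without PMA and 49.63 points above it with PMA (exact permutation p = 0.1 for each, the smallest that 3 against 3 libraries allow). The share of dE9 differed from WT by -43.6 and -48.19 points (exact permutation p = 0.2 for each, the smallest that 3 against 2 allow). The iE9 share exceeded WT by 14.59 points without PMA (exact permutation p = 0.2) and by 1.44 points with PMA (p = 1.0). The latter was not separated from WT. These samples are therefore called the libraries labelled iE9, and directions concern that label. The PMA difference in share was 1.38 points in WT (exact permutation p = 1.0, where 2 against 2 libraries allow no p under 0.333), -3.22 in dE9 (p = 0.1) and -11.77 in iE9 (p = 0.3). Over protein-coding transcripts alone the WT difference was 14.13 points, dE9 lay -61.18 points from WT with PMA, and iE9 lay -3.11 points from WT with PMA. Leaving out 1 library moved the iE9 difference from WT with PMA between -5.13 and 6.78 points.

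HDAC7 itself rose with PMA in each line. It rose from 51.9 ± 8.76 to 241 ± 4.62 CPM in WT (4.64-fold, adjusted p = 0.000128), from 53.1 ± 6.18 to 188 ± 54.5 CPM in dE9 (3.54-fold, 3.82e-05), and from 168 ± 37.4 to 351 ± 47.2 CPM in iE9 (log2 1.06 ± 0.21, 0.00234). Without PMA, HDAC7 was higher in the libraries labelled iE9 than in dE9 (log2 1.66 ± 0.22, adjusted p = 0.00224) and WT (1.70 ± 0.25, 0.00698). With PMA it was higher than in dE9 (0.90 ± 0.21, 0.0393), a call lost in 5 of 6 fits without 1 library, while the difference from WT did not pass (0.54, adjusted p = 0.328). Transcripts without exon 9 had a TPM of 13.18 and 37.74 in unstimulated and PMA-treated iE9.

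**Figure D2:**
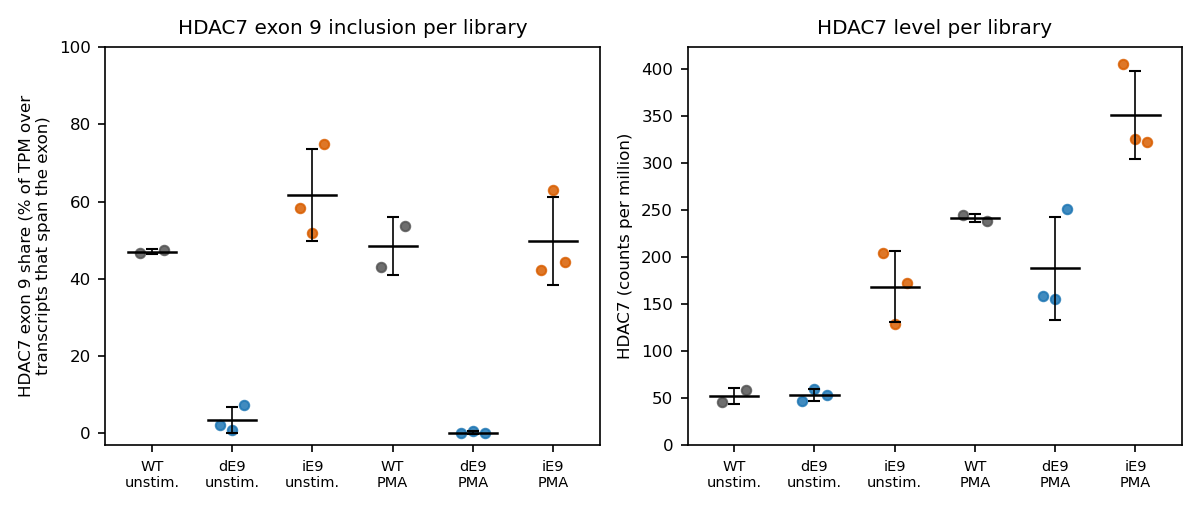
The left panel shows the exon 9 share (percent of TPM) and the right panel the HDAC7 level (CPM), with 1 point per library and the group mean ± SD. The dE9 libraries lie at 7.37% or lower, and the PMA-treated iE9 libraries span the WT values.

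CD69, an early activation antigen, rose with PMA in WT from 11.8 ± 1.38 to 401 ± 1.8 CPM (n = 2 each; log2 5.09 ± 0.41, adjusted p = 5.98e-06). The costimulatory receptor gene CD28 rose from 8.45 ± 1.13 to 297 ± 17.6 CPM (5.14 ± 0.92, 0.00157), and IL2RA from 0.122 to 12.4 ± 3.29 CPM (6.56 ± 1.3, 0.00291). RAG1 fell 90.8-fold, from 846 ± 137 to 9.32 ± 0.334 CPM (adjusted p = 3.44e-06), and the growth regulator MYC 42.5-fold, from 264 ± 26.6 to 6.2 ± 1.17 CPM (1.3e-05). TERT fell 36.4-fold from 11.5 ± 3.22 CPM (0.00249). CD3E (log2 0.88, adjusted p = 0.0588), CD5 (0.90, 0.627) and NR4A1 (1.10, 0.214) did not pass.

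By the naming rule on level and non-overlap, genes that rose most in WT included the histamine-synthesizing enzyme HDC (from 0.561 ± 0.129 to 89 ± 4.58 CPM, 156-fold, adjusted p = 0.00339) and the calcium channel TRPC6 (from 0.182 to 44.6 ± 1.12 CPM, 230-fold). KRT79, CD300A and GPR84 had 0 counts without PMA and were at least 41.5-fold, 33.4-fold and 33.2-fold higher with it. Counts of 1 to 3 without PMA gave ratios of 245 for BBOX1 (interval 43.5 to 9700), 179 for SEMA4A (60.8 to 868), 185 for PGLYRP4 (50.8 to 1530) and 172 for LYL1 (58.5 to 835). KRT3 rose 224-fold, and both keratins are uncertain because members of that family share sequence. DCLK3 fell by a ratio of 203 (36.1 to 8080). C11orf74 fell 54.4-fold, next to RAG1 and overlapping RAG2 on chromosome 11, so reads near their shared boundary are uncertain. GPRC5B (50.6-fold), CCDC26, KANK4, LINC01226 and FA2H (35.1-fold) also fell.

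Of 15 MAPK feedback regulators, genes that restrain ERK signalling, 12 rose with PMA in WT, 1 fell and 2 did not pass (13 and 1 adjusted over the list alone), led by DUSP6 (log2 6.03 ± 0.41), PHLDA1 (4.55 ± 0.38), SPRY4 (4.41 ± 0.63) and DUSP4 (4.40 ± 0.61). Camera gave adjusted p = 3.36e-08, and adjusted p = 0.0811 with an estimated correlation. Of 17 AP-1 and EGR immediate early factors 10 rose and 7 did not pass (11 adjusted over the list alone), among them IER3 (4.84 ± 0.40), EGR2 (4.62 ± 0.43) and EGR1 (4.38 ± 0.37). That list had adjusted p = 6.14e-07, and adjusted p = 0.123 with an estimated correlation. Of 19 NF-kB members and targets 10 rose, including TNFAIP3 (3.06 ± 0.53), RELB (2.21 ± 0.30) and TRAF1 (2.20 ± 0.33), and 9 did not pass (10 adjusted over the list alone). Its adjusted p was 0.000745, and adjusted p = 0.239 with an estimated correlation. PKC and diacylglycerol signalling genes went both ways, with 6 of 19 risen, such as DGKA (2.53 ± 0.34) and PRKD2 (1.52 ± 0.18), 3 fallen, such as RASGRP1 (-1.85 ± 0.36), and 10 not passed (6 and 3 adjusted over the list alone; camera adjusted p = 0.0587).

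Of 20 co-receptors and surface molecules 8 rose with PMA in WT, 1 fell and 11 did not pass (10 and 1 adjusted over the list alone; camera adjusted p = 0.00229, and adjusted p = 0.313 with an estimated correlation). BTLA (log2 7.06 ± 1.10), CD226 (3.96 ± 0.53) and CD48 (3.79 ± 0.65) rose, and CD1D fell (-2.11 ± 0.34). Of 12 activation markers 7 rose, 1 fell and 4 did not pass (9 and 1 adjusted over the list alone), with CD40LG at 5.52 ± 0.68 and CD38 at 1.75 ± 0.35. Their adjusted p was 0.000492, and adjusted p = 0.239 with an estimated correlation. Of 17 genes of the T cell receptor complex and its proximal signalling 9 rose, such as LCP2 (2.85 ± 0.28) and TRAC (3.53 ± 0.74), and 8 did not pass (11 adjusted over the list alone). Camera gave adjusted p = 7.48e-05, and adjusted p = 0.239 with an estimated correlation. Of 15 antigen presentation genes 8 rose and 7 did not pass (9 adjusted over the list alone; 0.000459, and adjusted p = 0.324 with an estimated correlation), such as HLA-E (3.11 ± 0.49), a member of a gene family whose reads can be split between copies. Of 21 interferon response genes 9 rose, 1 fell and 11 did not pass (10 and 1 adjusted over the list alone), with MX2 at 3.58 ± 0.29 and IFIT2 at 3.02 ± 0.43 (0.00187, and adjusted p = 0.239 with an estimated correlation).

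Of 17 ribosome biogenesis genes 15 fell with PMA in WT and 2 did not pass (17 adjusted over the list alone), including NOLC1 (log2 -2 ± 0.24), BOP1 (-1.59 ± 0.20) and DKC1 (-1.53 ± 0.21). Camera gave adjusted p = 6.34e-11, and adjusted p = 0.123 with an estimated correlation. Of 23 cell cycle genes 16 fell and 7 did not pass (22 adjusted over the list alone), such as the replication licensing genes MCM2 (-2.42 ± 0.51) and MCM4 (-2.73 ± 0.64) and the mitotic checkpoint kinase BUB1 (-2.33 ± 0.46). That list had a median of -2.03 and adjusted p = 3.03e-08, and adjusted p = 0.313 with an estimated correlation. Of 18 cholesterol and fatty acid synthesis genes 7 fell and 11 did not pass (7 adjusted over the list alone), with ACACA at -1.78 ± 0.19 and FASN at -1.43 ± 0.22 (0.0001, and adjusted p = 0.305 with an estimated correlation). Of 17 glycolysis genes 2 rose, including the glucose transporter SLC2A3 (3.08 ± 0.53), 7 fell, including LDHA (-2.15 ± 0.38), and 8 did not pass (2 and 9 adjusted over the list alone; 0.0193, and adjusted p = 0.369 with an estimated correlation). Of 27 splicing regulators 11 fell, such as SRSF1 (-0.98 ± 0.21), 2 rose, such as CELF2 (2.22 ± 0.26), and 14 did not pass (14 and 2 adjusted over the list alone; 0.00111, and adjusted p = 0.202 with an estimated correlation).

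Of 11 cytokines and chemokines 3 rose with PMA in WT, namely IL16 (log2 5.60 ± 0.58), CSF2 and CXCL8, and 8 did not pass (4 adjusted over the list alone; 0.00414, and adjusted p = 0.239 with an estimated correlation). Of 7 natural killer and cytotoxic markers 3 rose, namely GZMA (6.54 ± 1.18), PRF1 (5.24 ± 0.97) and FCER1G, and 4 did not pass (3 adjusted over the list alone; 0.00872, and adjusted p = 0.305 with an estimated correlation). Of 15 p53 targets 5 rose, such as ZMAT3 (1.26 ± 0.23), and 10 did not pass (5 adjusted over the list alone; 0.0169, and adjusted p = 0.239 with an estimated correlation). Of 15 apoptosis regulators 7 rose, such as CFLAR (2.36 ± 0.21), 2 fell, such as BCL2L11 (-1.82 ± 0.23), and 6 did not pass (7 and 2 adjusted over the list alone; 0.0283, and adjusted p = 0.313 with an estimated correlation). Of 22 adhesion and migration genes 6 rose, such as CCR4 (5.37 ± 0.89), 2 fell and 14 did not pass (6 and 2 adjusted over the list alone; 0.0191, and adjusted p = 0.313 with an estimated correlation).

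The remaining lists did not pass camera in WT. Of 25 thymocyte transcription factors and rearrangement genes 9 rose, such as LMO2 (log2 6.72 ± 0.74) and GATA3 (2.92 ± 0.26), 4 fell, such as RAG2 (-5.00 ± 0.56), and 12 did not pass (10 and 7 adjusted over the list alone; 0.279). The HDAC family had 2 risen, including HDAC5 (2.40 ± 0.38), 2 fallen, including HDAC1 (-0.68 ± 0.21), and 10 of 14 not passed (4 and 3 adjusted over the list alone; 0.466). The MEF2 and NR4A axis had 4 risen, including NR4A3 (4.27 ± 0.77) and MEF2D (1.11 ± 0.26), 1 fallen and 5 of 10 not passed (4 and 3 adjusted over the list alone; 0.466). Camera gave 0.0996 for the 14-3-3 proteins (1 of 7 fell, 2 adjusted over the list alone), 0.341 for the NOTCH pathway (2 rose and 3 fell of 14, the same adjusted over the list alone) and 0.903 for cyclin-dependent kinase inhibitors and D cyclins (3 rose and 2 fell of 13, 3 and 4 adjusted over the list alone). It gave 0.118 for the unfolded protein and integrated stress response (1 rose and 5 fell of 15, 1 and 6 adjusted over the list alone) and 0.494 for histone-modifying enzymes (3 rose and 5 fell of 22, 3 and 6 adjusted over the list alone). It gave 0.222 for 13 mitochondrially encoded genes (0 called) and 0.327 for replication-dependent histones (1 of 6 rose). Marker lists with too few tested members for camera were counted only: 1 of 1 myeloid marker (S100A9) and 1 of 3 fibroblast or endothelial markers (COL3A1) rose, while 0 of 4 B cell, 0 of 2 erythroid and 0 of 2 epithelial markers were called.

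In all, PMA changed 4038 genes in WT, 2003 higher and 2035 lower (edgeR), and 2957 of them changed at least 2-fold. The count depended on each of the 4 WT libraries, being 1419 without unstimulated library 1, 1904 without unstimulated library 2, 1704 without PMA library 1 and 1669 without PMA library 2. A fit of only the WT libraries called 8284 genes and limma voom with group weights 8754. Of 128 named called results, 89 were called in every such fit that left out 1 library.

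**Figure D3:**
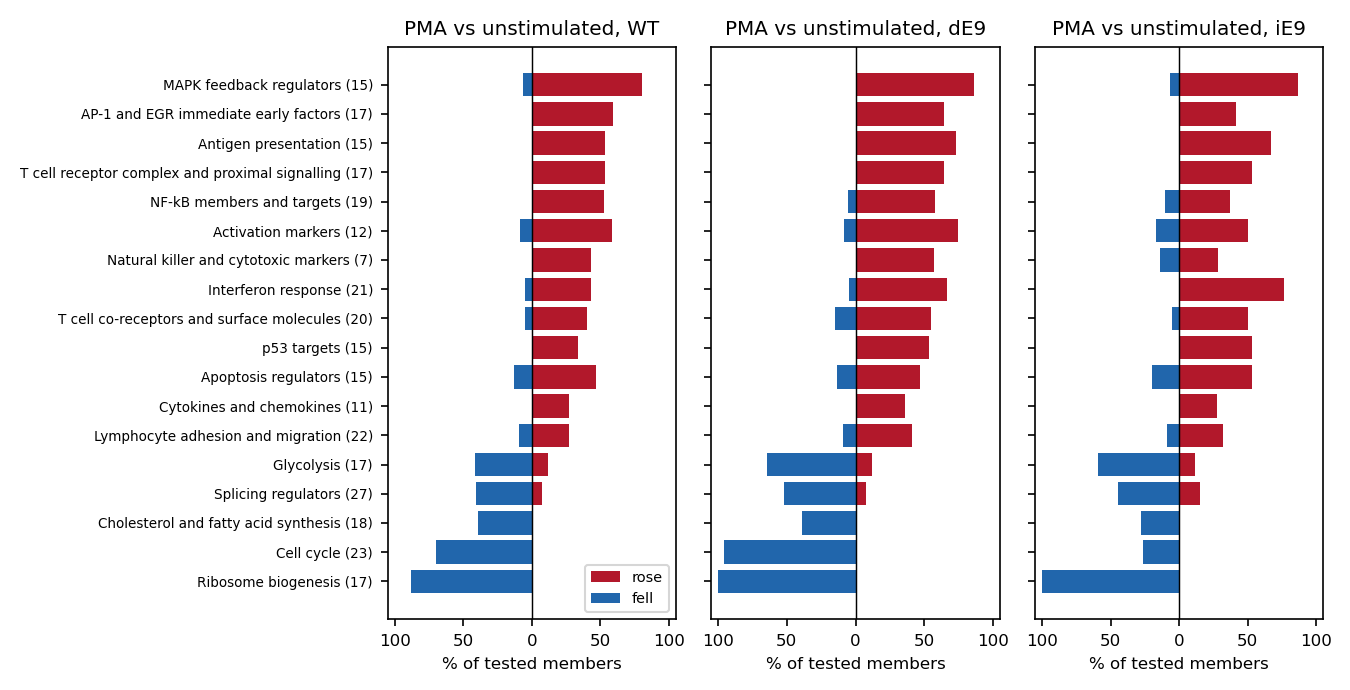
Bars give the percent of tested members (number in brackets) of each list that rose (right) or fell (left) with PMA in WT, dE9 and iE9, for lists that passed camera in WT. Of 23 cell cycle genes 22 fell in dE9 and 6 in iE9, and 0 passed as differing in response.

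The edited lines responded to PMA with many of the same genes. CD69 rose in dE9 from 6.4 ± 0.721 to 249 ± 97.6 CPM (log2 5.28 ± 0.34, adjusted p = 4.05e-07) and in iE9 from 26.4 ± 6.63 to 607 ± 153 CPM (4.53 ± 0.32, 9.15e-07; n = 3 each). CD28 rose from 22.7 ± 22.5 to 389 ± 308 CPM in dE9 (4.09, 0.000569) and from 64.6 ± 36 to 550 ± 193 CPM in iE9 (3.09, 0.00372). IL2RA rose to 8.54 ± 7.06 CPM in dE9 (6.74, 0.000394) and to 9.32 ± 3.81 CPM in iE9 (5.85, 0.000856). RAG1 fell 49.4-fold in dE9, to 6.53 ± 1.02 CPM, and 97.5-fold in iE9, to 2.16 ± 0.46 CPM. CD3E rose in dE9 (0.74 ± 0.26, 0.0373) but did not pass in iE9 (0.28, adjusted p = 0.447). CD5 did not pass in dE9 (0.74, 0.592) or iE9 (1.26, 0.366), nor did NR4A1, an orphan nuclear receptor (0.82, 0.225, and -1.26, 0.0818). With the block for library numbers CD5 passed in dE9 (0.77, 0.00163) and iE9 (1.17, 0.000116), and in iE9 CD3E (0.33, 0.0385) and NR4A1 (-1.30, 0.0372) passed too.

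By the same rule GBP4 (ratio 507, interval 90.7 to 20100), PGLYRP4 (333, 59.4 to 13200), KRT3 (208-fold), KRT79 (158, 43.4 to 1310) and HDC (119-fold, to 160 ± 228 CPM) rose in dE9. C11orf74 and RAG2 (45.0-fold each), the thyrotropin receptor gene TSHR (27.9-fold, from 74.7 ± 30.2 CPM) and MYC (26.2-fold, from 200 ± 37.2 CPM) fell. In iE9, CD300A rose at least 58.9-fold from 0 counts, the survival gene BCL2A1 156-fold to 19.3 ± 5.11 CPM, IL31RA by a ratio of 156 (53 to 759) and KRT79 by 165 (45.3 to 1370). The readthrough gene BIVM-ERCC5 (at least 88.0-fold higher) and the antisense gene CERS6-AS1 (at least 55.3-fold lower) are uncertain, since they overlap other genes. C11orf74 fell by a ratio of 388 (69.3 to 15400), RAG2 42.3-fold and TMEM52 41.1-fold in iE9.

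With PMA, MAPK feedback regulators had 13 of 15 members risen and 2 not passed in dE9 (13 adjusted over the list alone; camera adjusted p = 6.6e-08, and adjusted p = 0.0916 with an estimated correlation). In iE9 13 rose, 1 fell and 1 did not pass (13 and 1 adjusted over the list alone; 1.24e-07, and adjusted p = 0.0599 with an estimated correlation). DUSP6 rose by 5.89 ± 0.34 and 5.25 ± 0.32 on the log2 scale in dE9 and iE9. AP-1 and EGR factors had 11 of 17 risen and 6 not passed in dE9 (12 adjusted over the list alone; 5.78e-07, and adjusted p = 0.103 with an estimated correlation), with EGR1 at 5.31 ± 0.32. In iE9 7 rose and 10 did not pass (9 risen and 1 fallen adjusted over the list alone; 0.000182, and adjusted p = 0.228 with an estimated correlation), with EGR1 at 4.37 ± 0.30. Interferon response genes had 14 of 21 risen, 1 fallen and 6 not passed in dE9 (14 and 1 adjusted over the list alone; 1.18e-05, and adjusted p = 0.103 with an estimated correlation). In iE9 16 rose and 5 did not pass (16 adjusted over the list alone; 3.1e-07, and adjusted p = 0.0599 with an estimated correlation). Antigen presentation genes had 11 of 15 risen and 4 not passed in dE9 (11 adjusted over the list alone; 2.48e-05, and adjusted p = 0.307 with an estimated correlation). In iE9 10 rose and 5 did not pass (10 adjusted over the list alone; 0.000182, and adjusted p = 0.383 with an estimated correlation).

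Of 15 p53 targets 8 rose and 7 did not pass in each edited line, with 9 in dE9 and 10 in iE9 adjusted over the list alone. Camera gave 0.0046 in dE9 and 0.000599 in iE9, and adjusted p = 0.219 and 0.137 with an estimated correlation. CDKN1A, which encodes the cell cycle inhibitor p21, rose by 2.99 ± 0.44 in dE9 and 3.97 ± 0.46 in iE9 on the log2 scale. Ribosome biogenesis genes fell in all 17 members in dE9 and in iE9, also adjusted over the list alone (6.08e-12 and 1.49e-13, and adjusted p = 0.103 and 0.0599 with an estimated correlation). Cell cycle genes fell in 22 of 23 members in dE9 and 1 did not pass (23 adjusted over the list alone; median -2.23, 6.08e-12, and adjusted p = 0.286 with an estimated correlation). In iE9 6 fell, including MCM4 (-1.62 ± 0.50) and BUB1 (-1.2 ± 0.36), and 17 did not pass (6 adjusted over the list alone; median -1.04, 0.000259, and adjusted p = 0.65 with an estimated correlation). Natural killer markers rose in dE9 (4 of 7, 3 not passed, 4 adjusted over the list alone; 0.0233, and adjusted p = 0.342 with an estimated correlation). In iE9 the markers GZMA (2.84 ± 0.78) and FCER1G rose, KLRD1 fell (-2.94 ± 0.77) and 4 did not pass (2 and 1 adjusted over the list alone; 0.268). In dE9 the erythroid markers HBA1 (3.68 ± 1.16) and HBA2 (4 ± 1.36) rose, near-identical genes that share reads. With the block HBA2 (3.32, adjusted p = 0.16) and COL3A1 (from 3.70, 0.0177, to 2.49, 0.0991) did not pass in dE9.

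Co-receptors had 11 risen, 3 fallen and 6 of 20 not passed in dE9 (12 and 3 adjusted over the list alone; 0.00483), and 10 risen, 1 fallen and 9 not passed in iE9 (10 and 1 adjusted over the list alone; 0.00153). Activation markers had 9 risen, 1 fallen and 2 of 12 not passed in dE9 (9 and 1 adjusted over the list alone; 0.00146), and 6, 2 and 4 in iE9 (7 and 2 adjusted over the list alone; 0.00821). The T cell receptor complex had 11 of 17 risen in dE9 (13 adjusted over the list alone; 0.000102) and 9 in iE9 (9 adjusted over the list alone; 0.000182). With an estimated correlation these lists had adjusted p = 0.342, 0.266 and 0.266 in dE9 and 0.327, 0.327 and 0.288 in iE9. The block for library numbers ended the iE9 calls of apoptosis regulators (8 risen and 3 fallen of 15, from 0.0428 to 0.0662) and cholesterol synthesis (5 fallen of 18, from 0.0492 to 0.0687). It called mitochondrially encoded genes in dE9 (0.0548 to 0.00271) and iE9 (0.244 to 0.0371), and apoptosis regulators in dE9 (0.0601 to 0.0483). The mitochondrial share was highest in the iE9 libraries numbered 1, at 9.17% and 12.81%, and without both of them those iE9 calls were also lost (0.0521 for apoptosis, 0.055 for cholesterol synthesis), while mitochondrially encoded genes passed (0.0304). Without both dE9 libraries numbered 1, dE9 lost cholesterol synthesis (7 fallen of 18, from 0.00178 to 0.0545) and adhesion genes (9 risen and 2 fallen of 22, from 0.0228 to 0.0738).

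NF-kB members and targets had 11 risen, 1 fallen and 7 of 19 not passed in dE9 (12 and 2 adjusted over the list alone; 0.00146), and 7, 2 and 10 in iE9 (9 and 3 adjusted over the list alone; 0.00203). Cytokines had 4 of 11 risen in dE9 (4 adjusted over the list alone; 0.00452) and 3 in iE9 (3 adjusted over the list alone; 0.00705). PKC genes had 8 risen and 3 fallen of 19 in dE9 (9 and 3 adjusted over the list alone; 0.0371), and 7 and 2 in iE9 (7 and 3 adjusted over the list alone; 0.0145). With an estimated correlation these had adjusted p = 0.285, 0.266 and 0.286 in dE9 and 0.307, 0.288 and 0.288 in iE9. Splicing regulators had 2 risen and 14 fallen of 27 in dE9 (2 and 15 adjusted over the list alone; 0.000503), and 4 and 12 in iE9 (4 and 12 adjusted over the list alone; 0.0194). Glycolysis had 2 risen and 11 fallen of 17 in dE9 (2 and 11 adjusted over the list alone; 0.013), and 2 and 10 in iE9 (2 and 12 adjusted over the list alone; 0.0217). Their estimated-correlation tests gave adjusted p = 0.117 and 0.342 in dE9 and 0.288 and 0.466 in iE9. Adhesion genes did not pass in iE9 (7 risen and 2 fallen of 22; 0.21). Thymocyte factors did not pass in dE9 (10 risen and 6 fallen of 25; 0.398) or iE9 (8 and 6; 0.754), where the median of -0.08 and mean of -0.21 had the opposite sign to the test.

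PMA changed 6060 genes in dE9 (3082 higher, 2978 lower) and 4892 in iE9 (2283 higher, 2609 lower) by edgeR. Calls shared with WT in the same direction were 1822 higher and 1884 lower in dE9, where independent lists would share 342 and 335. They were 1423 higher and 1519 lower in iE9, against 253 and 294. In all 3 lines 1377 genes rose and 1460 fell, while 0 moved in opposite directions in WT and dE9, and 6 in WT and iE9. The iE9 count ranged from 3282 to 5428 and the dE9 count from 4808 to 6713 with 1 library left out. The block for library numbers gave 8174 genes in dE9 and 7200 in iE9.

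No gene passed as differing in PMA response between lines. For dE9 against WT edgeR called 0 genes (282 at an unadjusted p under 0.05; DESeq2 1). For iE9 against WT it called 0 (1022 at an unadjusted p under 0.05; DESeq2 62; voom 16), and for iE9 against dE9 0 (1239; DESeq2 136). The block for library numbers called 35 genes for iE9 against WT and 61 for iE9 against dE9. Without PMA-treated dE9 library 1, 22 genes were called for dE9 against WT and 461 for iE9 against dE9, and 15 for iE9 against dE9 without PMA-treated dE9 library 3. Without unstimulated iE9 library 3, 2 were called for iE9 against WT. For NR4A1 the difference in log2 response was -2.36 between iE9 and WT (adjusted p = 0.663) and -2.08 between iE9 and dE9 (0.54). For CD28 it was -2.05 between iE9 and WT (0.926), and -1.97 with the block (0.0303).

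Cell cycle genes as a list, however, differed in their response to PMA. Their fall was weaker in iE9 than in dE9, by a median of 1.2 on the log2 scale (camera adjusted p = 1.11e-14), and weaker than in WT by 0.88 (3.28e-05), with 0 of 23 members passing on their own, also adjusted over the list alone. With an estimated correlation these lists had adjusted p = 0.598 and 0.543. In dE9 the cell cycle response lay below that of WT (median -0.20, 0.000132, and adjusted p = 0.968 with an estimated correlation). The iE9 response was higher than that of WT for cholesterol synthesis (0.47, 0.000525, and adjusted p = 0.543 with an estimated correlation) and lower for natural killer markers (-1.89, 0.00642, and adjusted p = 0.543 with an estimated correlation). Between iE9 and dE9, AP-1 factors (-0.84, 0.0146), natural killer markers (-2.08, 0.0454), histone-modifying enzymes (0.35, 0.00329) and splicing regulators (0.17, 0.0241) also differed. Their estimated-correlation tests gave adjusted p = 0.598, 0.687, 0.525 and 0.598. Without both iE9 libraries numbered 1, whose mitochondrial share was 9.17% and 12.81%, the natural killer call was lost (0.0579) and mitochondrially encoded genes passed (0.0422), as did the stress response between iE9 and WT (0.0422). Without both dE9 libraries numbered 1 the cell cycle list had 1.4e-29 between dE9 and WT and 4.31e-38 between iE9 and dE9, and the calls of AP-1 factors (0.0697), splicing regulators (0.063) and natural killer markers (0.0697) were lost, while cholesterol synthesis (0.00722), interferon response (0.00215) and histone-modifying enzymes (0.0367) passed between dE9 and WT. The stress response list differed between dE9 and WT (0.34, 0.000174, and adjusted p = 0.367 with an estimated correlation).

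The block for library numbers added calls of a different response. Between iE9 and WT the block called activation markers (from 0.1 to 0.0402), the NOTCH pathway (0.129 to 0.0337) and the stress response (0.1 to 0.0337). Between iE9 and dE9 it called the NOTCH pathway (0.183 to 0.0274), cholesterol synthesis (0.116 to 0.0169), antigen presentation (0.183 to 0.0169) and adhesion genes (0.168 to 0.0274). Between dE9 and WT it called antigen presentation (0.106 to 0.00122).

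Between dE9 and WT without PMA no gene passed, although genes of the integrated stress response and cholesterol synthesis lay lower in dE9 as lists. Of 15 stress response genes 0 passed over all genes and 4 were lower adjusted over the list alone (list median log2 -0.48, camera adjusted p = 5.09e-07, and adjusted p = 0.098 with an estimated correlation). DDIT4, an inhibitor of mTORC1 signalling, was at -1.98 ± 0.27 (adjusted p = 0.0529) and ASNS, asparagine synthetase, at -1.53 ± 0.39 (adjusted p = 0.753). Of 18 cholesterol and fatty acid synthesis genes 0 passed and 2 were lower adjusted over the list alone, namely INSIG1 (-1.11 ± 0.32) and FDPS (-0.87 ± 0.25). That list had a median of -0.51 and adjusted p = 8.17e-12, and adjusted p = 0.244 with an estimated correlation. Of 17 AP-1 and EGR factors 0 passed and 2 were lower adjusted over the list alone, EGR1 (-1.70 ± 0.31) and EGR2 (-1.66 ± 0.42), with 0.000839 for the list, and adjusted p = 0.491 with an estimated correlation. These genes were named after their values were seen.

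Camera also placed MAPK feedback regulators (0.0206), thymocyte factors (0.0341) and co-receptors (0.0341) lower, and antigen presentation genes higher (median 0.57, 0.0341), in unstimulated dE9 than in WT. With an estimated correlation these had adjusted p = 0.543, 0.595, 0.87 and 0.904, and fry called 0 lists. With both dE9 libraries numbered 1 left out the calls of co-receptors (0.292), thymocyte factors (0.156) and antigen presentation (0.289) were lost. By edgeR 0 genes were called without PMA (560 at an unadjusted p under 0.05), against 21 by DESeq2, 41 by limma voom, 1 with a filter at 5 CPM, 1 with the length offset and 132 with no filter.

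With PMA, the antigen presentation list was higher in dE9 than in WT (median log2 0.72, camera adjusted p = 6.05e-07, and adjusted p = 0.487 with an estimated correlation) with 0 of 15 members passed, also adjusted over the list alone. B2M was at 0.72 ± 0.38 (adjusted p = 1). The interferon response was higher as well (0.28, 0.000631, and adjusted p = 0.429 with an estimated correlation). Cell cycle genes (-0.20, 7.79e-07), cholesterol synthesis (-0.30, 3.02e-05), co-receptors (-0.28, 0.00165), MAPK feedback regulators (-0.12, 0.00223), thymocyte factors (-0.27, 0.003) and AP-1 factors (-0.19, 0.0054) were lower. Their estimated-correlation tests gave adjusted p = 0.638, 0.487, 0.487, 0.429, 0.429 and 0.487, and fry called 0 lists. By edgeR 0 genes were called (459 at an unadjusted p under 0.05), against 9 by DESeq2 and 159 with no filter. Without PMA-treated dE9 library 1, which stood apart on the first component, 174 genes were called, 3 higher and 171 lower, and without both dE9 libraries numbered 1, 4 and 176. Without both, cell cycle genes had 5.94e-33, and the calls of cholesterol synthesis (0.0645), co-receptors (0.2), MAPK feedback regulators (0.135), thymocyte factors (0.0645) and AP-1 factors (0.0645) were lost. CD69 lay at -0.88 without and -0.69 with PMA in dE9 against WT (adjusted p = 1 for each).

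Without PMA the killer cell receptor gene KIR3DL2, of a family whose reads can be split between copies, was at 114 ± 55.6 CPM in libraries labelled iE9 (n = 3) and 3.65 ± 1.56 CPM in WT (n = 2), 31.3-fold higher (adjusted p = 0.000407). APP was at 2.76 ± 0.722 against 89.4 ± 7.7 CPM, 32.3-fold lower (1.58e-05). The terminal transferase gene DNTT was 82.3-fold lower, at 0.868 ± 0.39 against 73.6 ± 9.26 CPM (0.00872). The killer lectin receptor KLRD1 was 69.9-fold higher, from 0.119 CPM in WT to 9.09 ± 7.53 CPM. CD248 (53.9-fold) and the cytokine receptor IL21R (33.4-fold) were higher, and IL22RA2 was higher by a ratio of 274 (interval 48.9 to 10800). MAL (45.4-fold, adjusted p = 0.00216), TENT5C (27.7-fold) and TCEAL2 (26.2-fold) were lower.

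In unstimulated iE9 against WT camera passed 8 lists, each with adjusted p = 0.717 with an estimated correlation, and fry called 0. Of 7 natural killer markers 3 rose, namely KLRD1 (log2 6.13), NKG7 (4.81, adjusted p = 0.0304) and PRF1 (4.30, 0.0353), and 4 did not pass (5 risen and 1 fallen adjusted over the list alone; median 3.44, camera adjusted p = 0.00199). Of 22 adhesion and migration genes 3 rose, among them CCR7 (5.92, 0.012) and ICAM3 (1.46, 0.0251), and 19 did not pass (8 and 2 adjusted over the list alone; 0.0211). CD38 (1.45, 0.0465) rose among 12 activation markers (1 risen, 11 not passed, 5 adjusted over the list alone; 0.00165), and PDCD1, which encodes PD-1 (3.95, 0.0296), among 20 co-receptors (1 risen, 19 not passed, 6 and 1 adjusted over the list alone; 0.00573). Of 15 antigen presentation genes 0 passed over all genes and 7 were higher adjusted over the list alone (0.00165). Of 6 replication-dependent histones 1 rose and 5 did not pass (2 adjusted over the list alone; 0.0211). Cholesterol synthesis was lower, with 0 of 18 passed and 2 adjusted over the list alone (-0.32, 0.0211). Mitochondrially encoded genes were higher, with 0 of 13 passed (0.50, 0.0327), and the mitochondrial share was 9.17% in iE9 library 1. Of 25 thymocyte factors ID2 rose (4.03, 0.0175), TCF7 (-2.22, 0.0298), RAG1 (-2.01, 0.00979) and DNTT fell, and 21 did not pass (3 and 5 adjusted over the list alone; 0.355).

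In all 249 genes differed without PMA, 122 higher and 127 lower (edgeR; 2725 at an unadjusted p under 0.05). Leaving out 1 library gave 18 genes without WT library 1, 46 without WT library 2, and 87, 139 and 90 without iE9 libraries 1, 2 and 3. Of 26 named called results only those of APP, KIR3DL2 and MAL were called in each of these fits. DESeq2 called 846. Without both iE9 libraries numbered 1 the count was 99, and the lists of co-receptors (0.066), adhesion genes (0.0688) and mitochondrially encoded genes (0.649) no longer passed, while apoptosis regulators did (0.0481).

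With PMA the libraries labelled iE9 kept a lower level of APP than WT, at 0.987 ± 0.199 against 61.9 ± 19.5 CPM (62.5-fold, adjusted p = 4.26e-06). The phosphatase gene PPM1H was 75.5-fold lower (1.49 ± 0.988 against 115 ± 9.88 CPM, 0.000701), and SLIT2 63.6-fold lower (1.76 ± 0.474 against 113 ± 40.6 CPM, 0.00155). DNTT was 83.0-fold lower and BBOX1 lower by a ratio of 385 (interval 68.5 to 15200). KIR3DL2 was 18.2-fold higher (125 ± 41.3 against 6.83 ± 2.29 CPM, 0.000869), CGREF1 27.5-fold (19.3 ± 3.99 against 0.695 CPM, 0.00965), GNGT2 33.6-fold, the gelatinase gene MMP9 21.5-fold (0.0441) and IL22RA2 by a ratio of 95.3 (32.4 to 464). GNGT2 overlaps ABI3 on chromosome 17, so its level is uncertain. CDKN1A was higher in iE9 (log2 3.00 ± 0.51, 0.011).

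Of 25 thymocyte factors DNTT and RAG1 (log2 -2.11, adjusted p = 0.0176) were lower and 23 did not pass with PMA (2 higher and 9 lower adjusted over the list alone; camera adjusted p = 0.0164, and adjusted p = 0.647 with an estimated correlation). Of 21 interferon response genes 1 was higher and 20 did not pass (7 adjusted over the list alone; 0.014, and adjusted p = 0.647 with an estimated correlation). Antigen presentation (median 0.75, 0 of 15 passed, 6 higher adjusted over the list alone; 0.00409), co-receptors (0.88, 0 of 20; 0.014) and cell cycle genes (0.66, 0 of 23; 0.0137) were higher, each with adjusted p = 0.744 with an estimated correlation. Among antigen presentation genes, B2M was at 1.21 ± 0.39 (adjusted p = 0.164). Ribosome biogenesis was lower (-0.32, 0 of 17 passed, 1 adjusted over the list alone; 0.00409, and adjusted p = 0.647 with an estimated correlation). In all 203 genes differed, 60 (29.6%) higher and 143 lower (edgeR; 2562 at unadjusted p under 0.05). DESeq2 called 732 (43% higher) and voom 1021 (53.3%). The count was 24 and 38 without WT libraries 1 and 2, and 60, 65 and 73 without iE9 libraries 1, 2 and 3. The calls of APP, BBOX1, KIR3DL2, PPM1H and SLIT2, 5 of 16 named, held in each of these fits. With both iE9 libraries numbered 1 left out 84 genes were called, and the lists of co-receptors (0.139) and thymocyte factors (0.0607) did not pass, while p53 targets (0.0766 to 0.0177) and apoptosis regulators (0.386 to 0.0293) did.

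Between the 2 treatments, iE9 against WT shared 15 higher and 42 lower calls, against 0.405 and 1 for independent lists. The fitted log2 fold changes of dE9 and iE9 against WT correlated across genes at 0.55 without and 0.44 with PMA. As differences of mean log2 CPM they correlated at 0.5 and 0.4. Unchanged groups sharing controls gave 0.61 and 0.60 in 20 simulations with equal spread, but WT varied less, so these cannot be compared. With a different WT control per line, a split chosen afterwards, the correlation was 0.13 to 0.18 without and 0.05 to 0.13 with PMA.

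Without PMA, CD69 was higher in the libraries labelled iE9 than in dE9, at 26.4 ± 6.63 against 6.4 ± 0.721 CPM (log2 2.04 ± 0.30, adjusted p = 0.00394; n = 3 each). KIR3DL2 was 78.7-fold higher, at 114 ± 55.6 against 1.43 ± 0.396 CPM (1.84e-05). TRAC was 17.2-fold higher, at 123 ± 36.5 against 7.09 ± 6.9 CPM (0.00418), and the variable segment TRAV8-4 17.6-fold, at 31.9 ± 11.4 against 1.75 ± 1.56 CPM; segments share sequence and are uncertain. APP was 11.8-fold lower, at 2.76 ± 0.722 against 32.8 ± 10.7 CPM (0.000168), and the receptor phosphatase PTPRD 19.8-fold lower, at 0.499 ± 0.337 against 10.2 ± 1.49 CPM (0.000595).

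Also higher in iE9 were DHRS2 (ratio 97.8, interval 33.1 to 477), KLRD1 (40.9-fold, adjusted p = 0.00754), SNX20 (30.6-fold), LINC01748 (27.3-fold), CD248 (21.6-fold, 0.00544), ACSL5 (17.5-fold) and IL22RA2 (16.6-fold). TCEAL2 (63.0-fold), DNTT (43.9-fold), TENT5C (26.6-fold), CD9 (25.5-fold, 0.0369), MAL (22.7-fold), GPRASP1 (22.5-fold), RAB3IL1 (11.4-fold) and RFX8 (11.3-fold) were lower. DNTT spread widely in dE9, at 39.2 ± 39.3 CPM. CD28 (1.5, adjusted p = 0.28) and CD5 (1.2, 0.61) did not pass.

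Of 20 co-receptors PDCD1 (log2 4.89 ± 0.73, adjusted p = 0.00394) and CD48 (2.48 ± 0.51, 0.0268) were higher in unstimulated iE9 than in dE9 and 18 did not pass (7 adjusted over the list alone; median 1.51, camera adjusted p = 3.43e-06, and adjusted p = 0.304 with an estimated correlation). Of 12 activation markers CD69 and CD38 (2.09 ± 0.29, 0.00316) rose and 10 did not pass (5 adjusted over the list alone; 6.65e-05, and adjusted p = 0.304 with an estimated correlation). Of 17 AP-1 and EGR factors EGR1 (1.40, 0.0252) rose and 16 did not pass (7 adjusted over the list alone; 9.5e-05, and adjusted p = 0.304 with an estimated correlation). Of 22 adhesion genes CCR7 (4.98 ± 0.78, 0.00541) and ICAM3 (1.15, 0.0321) rose, the integrin gene ITGA5 fell (-1.42, 0.0422) and 19 did not pass (6 and 2 adjusted over the list alone; 0.0036, and adjusted p = 0.391 with an estimated correlation). Of 7 natural killer markers KLRD1 and NKG7 (3.51, 0.0327) rose and 5 did not pass (4 adjusted over the list alone; 0.00743, and adjusted p = 0.391 with an estimated correlation). Of 17 genes of the T cell receptor complex TRAC rose and 16 did not pass (3 adjusted over the list alone; 0.0036, and adjusted p = 0.422 with an estimated correlation). Of 25 thymocyte factors ID2 (3.97 ± 0.62, 0.00541) rose, TCF7 (-2.34 ± 0.43, 0.0142) and DNTT fell and 22 did not pass (5 and 3 adjusted over the list alone). That list had a negative median (-0.08) but a positive camera direction (0.823). DDIT4 (2.61 ± 0.26, 0.000235) rose in the stress response list, the death receptor gene FAS (1.26, 0.0438) among p53 targets, DLL1 (2.08, 0.0353) in the NOTCH pathway, PRKCH (1.03, 0.0325) among PKC genes and EBF1 (1.77, 0.0195) among B cell markers.

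With 0 members called over all genes, MAPK feedback regulators (median 0.39, 4 adjusted over the list alone; 0.00942), antigen presentation (0.64, 3 adjusted over the list alone; 0.0281), cytokines (1.17; 0.0339), cholesterol synthesis (0.27; 0.0499), replication-dependent histones (0.79, 1 adjusted over the list alone; 0.0499) and mitochondrially encoded genes (0.63; 0.0036) were higher. By the estimated correlation their adjusted p = 0.391, 0.657, 0.422, 0.657, 0.63 and 0.657. Ribosome biogenesis (-0.25; 0.00133), splicing regulators (-0.20; 0.0177), cell cycle genes (-0.34; 0.0377) and 14-3-3 proteins (-0.36; 0.0432) were lower, with adjusted p = 0.422, 0.391, 0.751 and 0.647 with an estimated correlation. By fry, co-receptors, activation markers and AP-1 factors (0.0322 each), splicing regulators and natural killer markers (0.0435 each) passed. With both iE9 libraries numbered 1 left out, calls were lost for mitochondrially encoded genes (0.105), 14-3-3 proteins (0.171), cytokines (0.0891), cell cycle genes (0.18), cholesterol synthesis (0.0565) and antigen presentation (0.153), and apoptosis regulators passed (0.0436). With both dE9 libraries numbered 1 left out the 14-3-3 call was lost (0.0703) and the stress response passed (0.00276).

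In all 311 genes differed without PMA, 173 of them higher in iE9 (edgeR; 2726 at an unadjusted p under 0.05), and DESeq2 called 867. The count was 155, 276 and 114 without dE9 libraries 1, 2 and 3, and 110, 168 and 133 without iE9 libraries 1, 2 and 3. With both iE9 libraries numbered 1 left out it was 152. Of 37 named called results 19 held in each fit with 1 library left out, including APP, CCR7, CD38, CD69, DDIT4, HDAC7, ID2, KIR3DL2, PDCD1, PTPRD and TRAC, while CD9, DLL1, FAS, GPRASP1 and RFX8 were lost in 5 of 6.

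**Figure D4:**
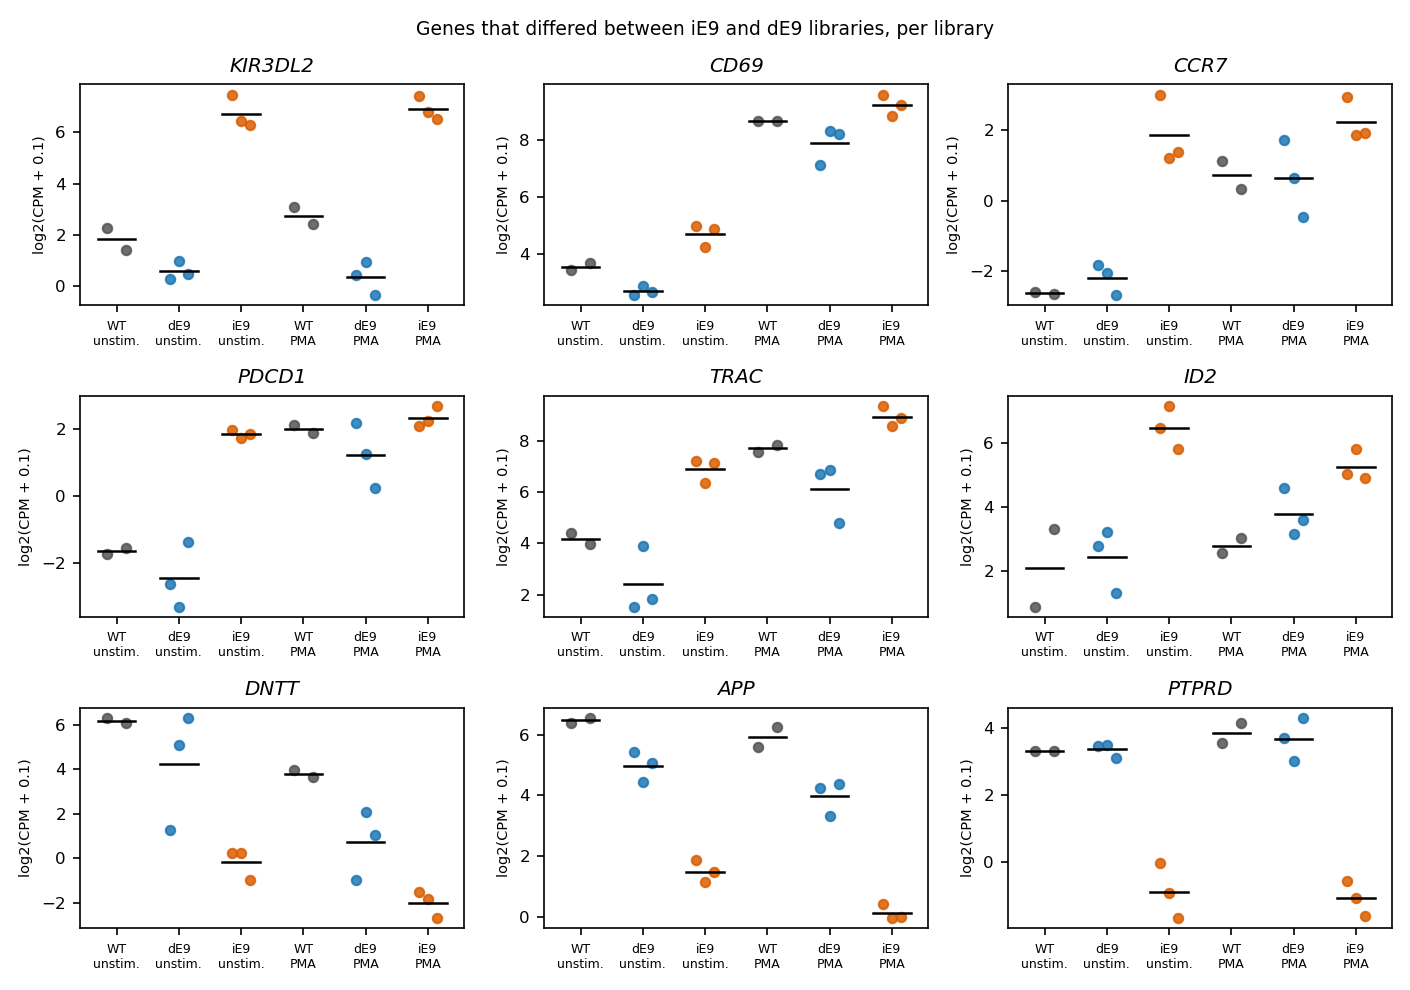
Each panel shows 1 gene as log2(CPM + 0.1) per library, with group means as lines. KIR3DL2, CD69, CCR7, PDCD1, TRAC and ID2 were higher, and DNTT, APP and PTPRD lower, in unstimulated iE9 than in unstimulated dE9 libraries.

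Genes that PMA raised in WT were, as a set, higher in unstimulated iE9 than in unstimulated dE9. Over the 2003 genes raised in WT the median log2 difference was 0.33 and 77.2% were higher, and over the 2035 genes lowered in WT it was -0.23 and 82.2% were lower. The shift between the medians was 0.56 (0.34 to 0.8 by iE9 library), and 0.43 without both iE9 libraries numbered 1. Limma camera gave p = 3.66e-15 for the raised and 1.83e-15 for the lowered set, and p = 0.0136 and 0.0965 with an estimated correlation. With PMA the shift was 0.14, and limma camera gave p = 0.0734 and 0.836, and p = 0.512 and 0.963 with an estimated correlation.

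**Figure D5:**
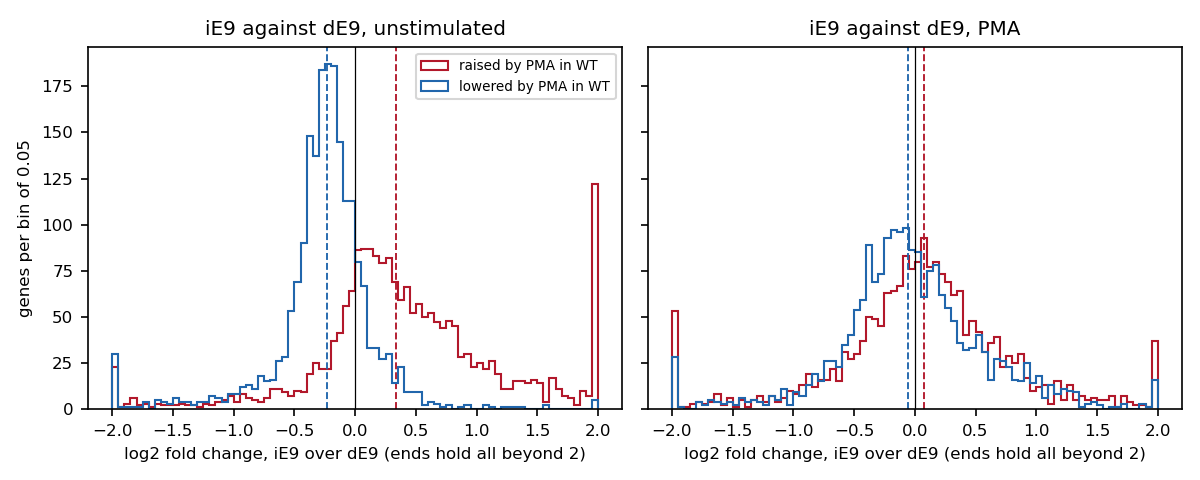
Histograms give the number of genes per bin of log2 fold change, iE9 over dE9, for genes raised or lowered by PMA in WT, with medians as dashed lines. The medians lie apart without PMA and close together with PMA.

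With PMA, CD69 was higher in the libraries labelled iE9 than in dE9, at 607 ± 153 against 249 ± 97.6 CPM (log2 1.28 ± 0.28, adjusted p = 0.0291; n = 3 each). KIR3DL2 was 97.5-fold higher (125 ± 41.3 against 1.25 ± 0.582 CPM, 1.12e-05), IL23R 34.4-fold (7.2 ± 2.81 against 0.209 CPM, 0.0241), IL22RA2 113-fold (0.00233) and ABI3 17.5-fold (20.5 ± 2.02 against 1.17 ± 0.58 CPM, 0.000583). CPA3 had 0 counts in iE9 and was at least 36.8-fold lower than in dE9, at 6.65 ± 3.56 CPM (0.000874). PTPRD was 34.7-fold lower (0.389 against 13.6 ± 5.98 CPM, 0.000136), PPM1H 56.2-fold (0.000717) and SLIT2 30-fold (0.00301).

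LINC01748 (50.9-fold), DHRS2 (17.5-fold), GNGT2 (16.4-fold, overlapping ABI3 and uncertain), the sodium channel SCN2A (14.4-fold), CGREF1 (12.1-fold) and C2orf40 (10.3-fold) were also higher in PMA-treated iE9. TCEAL2 (ratio 373, interval 66.5 to 14700), MLC1 (log2 -6.72 ± 1.22, from 17.6 ± 26.5 CPM in dE9), CDH4 (28.0-fold), the sodium channel SCN9A (27.0-fold), MAGEL2 (19.4-fold) and ADCYAP1 (18.1-fold) were lower. With 1 library left out TCEAL2 (log2 -9.99 to -5.82), MLC1 (-7.25 to -3.76), CDH4, ADCYAP1 and GNGT2 lost their calls in 3 of 6 fits, IL23R and C2orf40 in 4, and CD69 and MAGEL2 in 2. CD28 (0.50, adjusted p = 0.703), CD5 (1.71, 0.368) and NR4A1 (-1.58, 0.115) did not pass.

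Cell cycle genes were higher in PMA-treated iE9 as a list, with a median of 0.77 on the log2 scale and 0 of 23 members passed, also adjusted over the list alone (camera adjusted p = 1.56e-08, and adjusted p = 0.682 with an estimated correlation). Of 20 co-receptors CD1B (1.85 ± 0.36, adjusted p = 0.0167) and CD1C (2.67 ± 0.59, 0.0308) rose and 18 did not pass (5 adjusted over the list alone; 4.55e-06, and adjusted p = 0.527 with an estimated correlation). Of 18 cholesterol synthesis genes 1 rose and 17 did not pass (5 adjusted over the list alone; 0.00068, and adjusted p = 0.682 with an estimated correlation). RRS1 (-0.91, 0.0341) fell among 17 ribosome biogenesis genes and 16 did not pass (4 adjusted over the list alone; 0.00146, and adjusted p = 0.682 with an estimated correlation). The DNA dioxygenase gene TET3 (0.84, 0.035) rose among 22 histone-modifying enzymes and 21 did not pass (1 adjusted over the list alone; 0.00187, and adjusted p = 0.527 with an estimated correlation). That list alone passed fry (0.0146). Of 12 activation markers CD69 rose and 11 did not pass (2 and 1 adjusted over the list alone; 0.00697, and adjusted p = 0.682 with an estimated correlation).

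Within the HDAC family, HDAC9 (log2 -4.08 ± 0.88, adjusted p = 0.0278) and HDAC11 (-1.16 ± 0.23, 0.02) were lower and HDAC7 higher, while 11 of 14 did not pass (1 and 2 adjusted over the list alone; 0.29). The splicing regulator MBNL3 (1.33 ± 0.19, 0.00252) was higher, as were TRAC (2.63, 0.0285), BCL2A1 (2.63, 0.044), FAS (1.21, 0.041), DDIT4 (1.02, 0.0427) and ITGAE (0.85, 0.0368). TCF7 (-1.91, 0.0333), RAG1 (-1.60, 0.0324), RHOH (-1.19, 0.0301) and CASP9 (-0.98, 0.0484) were lower. With 1 library left out BCL2A1, FAS, DDIT4, ITGAE, TCF7, CASP9, TET3 and HDAC7 lost their calls in 5 of 6 fits, HDAC9, HDAC11, RAG1, RHOH, RRS1 and CD1C in 4, and TRAC in 3. Of 25 thymocyte factors 2 fell and 23 did not pass (2 adjusted over the list alone; 0.341). With both iE9 libraries numbered 1 left out, activation markers no longer passed (0.076), while p53 targets and apoptosis regulators did (0.0203 each).

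In all 471 genes differed with PMA, 199 higher and 272 lower in iE9 (edgeR; 3450 at an unadjusted p under 0.05), and DESeq2 called 1306. A fit of only the groups compared called 47. Limma voom called 127, 59.1% higher. The count was 1035, 278 and 722 without dE9 libraries 1, 2 and 3, and 120, 113 and 130 without iE9 libraries 1, 2 and 3. The balance turned without dE9 library 1 (685 higher, 350 lower) and without both dE9 libraries numbered 1 (691 and 333). Of 39 named called results 13 held in each fit with 1 library left out, including ABI3, CPA3, IL22RA2, KIR3DL2, MBNL3, PPM1H, PTPRD and SLIT2. Both treatments shared 46 higher and 63 lower calls, against 1.9 and 2.08 for independent lists.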

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

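The tests of a wrong label, of a batch that goes with the library number, of chromosome copies in iE9 alone, and of the share of PMA-treated cells that lowered genes need were chosen only after the results were seen.

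Several lists drew attention because their response to PMA differed between lines, by camera on the difference itself. The cell cycle list differed between dE9 and WT (adjusted p = 0.000132), iE9 and WT (3.28e-05) and iE9 and dE9 (1.11e-14). The stress response list differed between dE9 and WT (0.000174), and cholesterol synthesis (0.000525) and natural killer markers (0.00642) between iE9 and WT. Between iE9 and dE9, AP-1 and EGR factors (0.0146), splicing regulators (0.0241), histone-modifying enzymes (0.00329) and natural killer markers (0.0454) differed. With an estimated correlation 0 of these lists passed. Over 30 splits of the iE9 and dE9 libraries, 16 gave at least the 5 lists of the real labels (highest other 12). This cannot decide on chance, since splits that broke the numbered pairs can mix in the line difference. Genes of that response numbered 0 under the real labels, so 30 of 30 splits gave as many, with 1 at most.

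A few genes drew attention because PMA moved them in opposite directions in different lines, with no overlap between libraries. They were chosen after their values were seen, and no test of the difference passed. RHOU was at -1.50 ± 0.46 in WT and 1.19 ± 0.37 in iE9 on the log2 scale (adjusted p of the difference 0.27, edgeR). CD248 was at 2.97 ± 0.93 in WT and -1.89 ± 0.61 in iE9 (0.29), and LIME1 at 0.96 ± 0.27 and -0.65 ± 0.22 (0.27). SHISA2 was at 2.09 ± 0.51 in WT (0.201) and 1.52 ± 0.41 in dE9 (0.234), against -1.25 ± 0.41 in iE9.

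A retained-intron HDAC7 transcript (12: 47794807 to 47795604) was picked for its excess in unstimulated iE9 over WT, which is no test. Mean TPM was 10.49 in unstimulated and 19.8 in PMA-treated iE9, against 0.16 and 2.36 in WT and 0.99 and 4.0 in dE9. PMA-treated iE9 (8.26 to 26.03) overlapped dE9 (1.0 to 9.12). The interval lies beside exon 9, total HDAC7 was higher, and no cause was tested.

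The first pattern weighed was that libraries labelled iE9 held HDAC7 transcripts without exon 9. Of that TPM 84.4% lay on the 2 main transcripts of dE9, but these held 89.7% in WT too, so reads wrongly assigned by the estimate would lie there as well and are not excluded. Of genes that differed from WT without PMA, 92.8% kept their sign with PMA. This argues against a wrong label on the whole PMA group, not on part of it. Cells with an unedited allele could remain in the line, which these values neither show nor rule out.

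The second pattern was the shift of unstimulated iE9 libraries, relative to dE9, towards the PMA response. It kept 77% of its size without both iE9 libraries numbered 1, just over the 75% set beforehand, and was 0.80, 0.34 and 0.53 by library against -0.02, 0.12 and -0.12 in dE9, so that library alone does not account for it. Of 45 strongly raised genes 44.4% implied a share of PMA-treated cells within 2-fold of the median of 3.01% (range -9.13% to 24%). The 44.4% lay between the limits set beforehand, so this test could not decide. The median lowered gene would need a share of at least 14.6%. In each iE9 library lowered genes lay at -0.388 to -0.118, below the -0.039 to -0.023 that its raised genes allow, which excludes such a mixture as the whole cause. A biological difference of the line is confounded with how the line was derived and grown, and was not tested.

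The third pattern was that same-numbered libraries of an edited line deviated together, in iE9 clearly for number 1 only. A batch shared by number over all lines would correlate different lines, but at most 0.12 was seen, which excludes it. Chromosome copies that differ between the numbers could contribute in dE9. There 4 chromosome medians passed, all in number 2 (10, 12, 15 and 22), at -0.115 to -0.198. In iE9 0 of 69 passed, but the spread in number 1 could hide such shifts. Separate clones or cultures remain possible and were not tested.

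With 10 splits of 3 against 3 libraries, the share of splits as large as the real labels cannot go under 0.05. For genes, 1 of 10 splits, the real labels, reached 6060 with PMA in dE9 (highest other 3), 4892 in iE9 (highest other 0), 311 for iE9 against dE9 without PMA (highest other 0) and 471 with PMA (highest other 1). For lists, 1 of 10 reached 18 in dE9 (highest other 12), 17 in iE9 (highest other 14) and 16 for iE9 against dE9 without PMA (highest other 9). With PMA 5 of 10 reached the 6 lists of the real labels, and the highest other gave 13.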

How the results depend on the processing

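The block for library numbers within each line, limma voom, the fits without both iE9 or both dE9 libraries numbered 1, the fit without mitochondrial genes and the list tests under them were chosen only after the results were seen. Where a value below moved, the cause was not tested unless stated.

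Over all settings, 569 named results gave 9123 values, of which 8234 kept their direction and side of the threshold, 743 were weaker, 92 stronger and 54 reversed. Of 7665 values of called results 0 reversed. RLE factors left 568 of 569 the same, and leaving out mitochondrial genes all 569.

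The DESeq2 Wald test called 21 genes for dE9 against WT without PMA and 9 with PMA, 846 and 732 for iE9 against WT, and 867 and 1306 for iE9 against dE9. For the responses it called 1 (dE9 against WT), 62 (iE9 against WT) and 136 (iE9 against dE9). With no filter these counts were 132 and 159, 1220 and 1162, 1319 and 1801, and 49, 292 and 480. A filter at 5 CPM called 1 gene for dE9 against WT without PMA. A fit of only the groups compared has fewer libraries to estimate spread, and called 8284 genes with PMA in WT, 665 for iE9 against WT with PMA, 161 and 47 for iE9 against dE9, and 30 for the response of iE9 against WT. The length offset called 1 gene for dE9 against WT without PMA, 157 and 119 for iE9 against WT, and 180 and 304 for iE9 against dE9.

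An adjusted p under 0.01 is stricter by construction, and left 1853, 3771 and 2696 genes with PMA in WT, dE9 and iE9, 55 and 46 for iE9 against WT, and 78 and 90 for iE9 against dE9. At least 2-fold left 3845 in dE9 and 2838 in iE9 with PMA. A replicate block shared by all lines called 2 genes for the response of iE9 against WT. The block within lines called 6590 genes with PMA in WT, and 35 and 61 for the responses of iE9 against WT and dE9. Of 398 named results it left 386 the same; besides those given with the comparisons, CD3E (0.88) and CD5 (0.90) passed in WT, where numbers do not pair libraries, and LIME1 (0.51) and RHOU (-0.83) in dE9. With RLE factors 52.3% of calls were higher with PMA in WT and 50.4% in iE9, against 49.6% and 46.7%. Limma voom called 8754 genes with PMA in WT, 41 for dE9 against WT without PMA, 946 and 1021 for iE9 against WT, 127 for iE9 against dE9 with PMA, and 16 for the response of iE9 against WT.

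Without both iE9 libraries numbered 1 the counts were 99 and 84 for iE9 against WT, 152 for iE9 against dE9 without PMA and 2 for the response of iE9 against WT. Without both dE9 libraries numbered 1 they were 2 and 180 for dE9 against WT, 1024 for iE9 against dE9 with PMA and 396 for the response of iE9 against dE9. With 1 library left out, PMA calls ranged from 1419 to 1904 in WT, 4808 to 6713 in dE9 and 3282 to 5428 in iE9. Those of dE9 against WT ranged from 0 to 1 without and 0 to 174 with PMA, of iE9 against WT from 18 to 139 and 24 to 73, and of iE9 against dE9 from 110 to 276 and 113 to 1035. Response calls ranged from 0 to 22 (dE9 against WT), 0 to 2 (iE9 against WT) and 0 to 461 (iE9 against dE9).

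Under an estimated correlation 0 lists passed in any comparison. By fry 0 lists passed for either edited line against WT or for any response, 5 for iE9 against dE9 without PMA and 1 with PMA. Without both dE9 libraries numbered 1, camera called 4 and 3 lists for dE9 against WT, 5 for the response of dE9 against WT and 2 for that of iE9 against dE9. The block within lines called 6 and 9 lists for the responses of iE9 against WT and dE9.

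The exon 9 share over protein-coding transcripts was 14.13 points higher with PMA in WT, -61.18 points from WT in dE9 with PMA, and reversed to -3.11 for iE9 against WT with PMA. With 1 library left out, the PMA difference ranged from -3.97 to 6.71 in WT, -4.53 to -1.26 in dE9 and -18.34 to -5.16 in iE9. The difference from WT ranged from -45.56 to -42.29 and -53.53 to -42.85 in dE9, and 7.98 to 19.52 and -5.13 to 6.78 in iE9, where it also reversed to -3.90 without WT PMA library 1. For iE9 against dE9 it ranged from 51.58 to 63.11 and 43.06 to 53.41.

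The other reversals concerned genes that did not pass, and ranges here are over fits with 1 library left out. For HDAC7 in dE9 against WT without PMA the value was -0.02 with the replicate block and ranged from -0.12 to 0.23. CD5 in dE9 against WT was at 0.15 with the length offset, at 0.54 and 0.38 without both dE9 libraries numbered 1, and ranged from -0.80 to 0.56 without and -0.89 to 0.38 with PMA. The CD5 response ranged from -0.89 to 0.61 (dE9 against WT), -0.19 to 0.65 (iE9 against WT) and -0.26 to 1.24 (iE9 against dE9). IL2RA in iE9 against WT was at -0.05 without both iE9 libraries numbered 1 and ranged from -0.21 to 1.12 without PMA, and was at 0.25 with PMA under the replicate block. In dE9 against WT IL2RA ranged from -2.01 to 0.13 without and -0.96 to 0.03 with PMA. In iE9 against dE9 with PMA it was at -0.26 without both iE9 libraries numbered 1 and ranged from -0.44 to 0.54.

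The IL2RA response of dE9 against WT was -0.08 (replicate block), -0.21 (length offset) and -0.46 (voom), and ranged from -0.66 to 1.47. NR4A1 in iE9 against WT without PMA was at -0.03 (length offset) and -0.01 (voom), and ranged from -0.26 to 0.24. Its response of dE9 against WT was 0.04 (length offset) and ranged from -0.68 to 0.19. CD28 ranged from -1.94 to 0.16 for that response and from -0.48 to 0.72 in dE9 against WT with PMA, and CD69 from -0.02 to 0.47 for that response. CD3E in iE9 against dE9 with PMA was at -0.13 without both iE9 libraries numbered 1 and ranged from -0.14 to 0.25. MKI67 in iE9 against dE9 without PMA was at -0.20 without both and ranged from -0.20 to 0.30. The PMA effect on CD248 in dE9 was 0.02 (length offset), 0.05 (block within lines) and 0.09 (voom), and ranged from -0.50 to 0.53.

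Library totals of 14536537 to 21888896 counts leave 18073 genes tested, and genes with few counts carry wide counting intervals, such as 43.5 to 9700 for the BBOX1 ratio.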
